A study of Homo sapiens with 7 samples.

How the data were processed

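The series holds 7 CUT&RUN libraries of Rh4 cells made with an antibody against HA, per the labels. Of these, 6 were crosslinked: 2 with DMSO, 2 with 500 nM dTAG47 for 2 h and 2 for 4 h. The DMSO library without crosslinking was not analysed here. The deposited values are raw counts of reads per site, made by the authors and not normalized. Per the submitters' processing notes, the tools were Trimmomatic 0.32, Bowtie2, Genrich 0.6.1, DiffBind, DESeq2 and deepTools, with the hg19 build; their roles, order and settings, and whether duplicate reads were removed, are not given in the sources used here. How the sites were chosen is not given either, and a set chosen on DMSO libraries would favour falls.

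The table has 6 count columns, and 0 further columns of values were left aside. Column names give the treatment and a letter. The DMSO columns were taken as the crosslinked pair because only that DMSO group has 2 samples; their names do not state crosslinking. The letters A and B are not tied to replicate numbers in the labels. Coordinates are printed as the file gives them, and whether starts count from 0 or 1 is not stated, so they may be off by 1 base. The table names no genes and no hg19 annotation was used here, so sites are given by position. The planned gene lists, promoter classes, sequence motifs and crosslinking comparison were not run for these reasons. Sequencing depth outside the sites is unknown. Total counts in the sites ran from 110440 to 380057 per library, and the median tested site held between 13 and 50 reads, which limits precision at single sites.

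Sites were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 5575 and removed 207. Counts were tested with edgeR's quasi-likelihood test (R 4.3.3) in 1 fit of all 6 columns with treatment as the only term and 3 residual degrees of freedom, with Benjamini-Hochberg adjustment at a threshold of 0.05. The comparison of raw counts gave every library the same size and used no scaling, so any difference in depth stays in it. The relative comparison used totals in sites with TMM factors and cannot show a change common to most sites. The standard error of a log2 change was taken as its size over the square root of the F statistic. The biological coefficient of variation was 38.8% in the raw fit and 11.6% in the relative fit.

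Both comparisons were tested on simulated data with the real site means over 5575 sites, with 100 sites changed 2-fold and 100 changed 4-fold. The relative simulation used the real library sizes. The raw simulation gave every library the same size, so library-wide shifts entered it only as spread at each site. Its recovery may therefore not hold for the real libraries, whose shifts are shared by all sites. For 4 h against DMSO the raw test recovered 0% of the 2-fold and 8% of the 4-fold changes, and the relative test recovered 57% and 88%. For 2 h the raw test recovered 2% and 26%, and the relative test 58% and 95%.

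Tests, named-site rule and most alternatives were fixed before the data were examined. Named sites were the 10 largest relative falls and rises of each comparison with DMSO among sites past the threshold at which both treated columns lay on the same side of both DMSO libraries in counts divided by the library's total, and the 5 sites with the highest mean DMSO count. Alternatives were no filter, a fit of only the compared groups, a replicate block, DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings, a minimum log2 change of 1, and leaving out each library. Scaling on the 20 highest sites and counting the 4 h columns as 1 library were added after seeing the data. Further tests used Python 3.11.15 with scipy 1.17.1.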

Results

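Occupancy of chromatin by PAX3-FOXO1 was measured by CUT&RUN in Rh4 cells. Rh4 is an established rhabdomyosarcoma line that carries the PAX3-FOXO1 fusion, a transcription factor that joins the DNA-binding part of PAX3 to the activation domain of FOXO1. In the cells used here the fusion carried an FKBP degron and an HA tag, and an antibody against HA located it. CUT&RUN directs a nuclease to the antibody, so that DNA under the bound protein is released and sequenced. dTAG47, a small molecule that bridges the FKBP degron to an E3 ubiquitin ligase and so causes degradation of the tagged protein, was given at 500 nM for 2 h or 4 h, and DMSO served as the control. The values were raw read counts at 5782 sites on 24 chromosomes, each with an end 400 bases after its start in hg19. There were 2 crosslinked libraries each for DMSO, 2 h and 4 h.

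Total counts in the sites were 226067 and 380057 in the DMSO libraries A and B. They were 228300 and 110440 in the 2 h libraries A and B, and 151360 and 156845 in the 4 h columns A and B. The 4 h columns did not differ beyond the sampling noise (chi-square per degree of freedom 1.01 over 5575 sites, p = 0.24) and were counted as 1 sample in n and in means. The same measure was 2.09 for the DMSO pair and 1.96 for the 2 h pair. Unless stated otherwise, the tests below kept both 4 h columns as separate libraries, and their calls and adjusted p-values rest on that. Because the labels do not say that libraries came from separate cultures, p-values measure only the spread between these libraries, which may be technical.

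The first question was how much HA signal the sites lost as a whole when the tagged fusion was degraded. The mean total was 303062 ± 108887 (SD, n = 2) with DMSO, 169370 ± 83340 (SD, n = 2) after 2 h and 154102 after 4 h (n = 1). The 2 h mean was 55.9% and the 4 h mean 50.8% of the DMSO mean. At 97.8% of the 5575 tested sites the fitted count was lower at 4 h than with DMSO, and at 97.4% it was lower at 2 h. The median site had a count 1.91-fold lower at 2 h and 2.12-fold lower at 4 h (log2 −0.93 and −1.08). The median log2 change at 2 h was −1.66 without the 2 h library A and −0.47 without the 2 h library B. Without the DMSO library B it was −0.49 at 2 h and −0.65 at 4 h. The spread between libraries was as large as these differences: the 2 h library A held about as many reads as the DMSO library A. An exact two-sided permutation test of the log totals gave p = 0.667 for 2 h and p = 0.333 for 4 h, and 0.333 is the smallest p that 2 columns against 2 allow.

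The 5 sites with the most reads kept counts near their DMSO level. The highest DMSO count was at chr1:121484990-121485390, with 4842 and 4496 reads in the DMSO libraries, 4740 and 4330 at 2 h and 4720 and 4715 in the 4 h columns. The site chr7:61968821-61969221 had 2639 and 2368 reads with DMSO and 2413 and 2540 at 4 h. The site chr6:58778181-58778581 had 1637 and 1394 reads with DMSO and 1508 and 1537 at 4 h. At chr9:66971000-66971400 the counts were 1048 and 1014 with DMSO and 1029 and 988 at 4 h, and at chr2:92269319-92269719 they were 825 and 735 with DMSO and 721 and 784 at 4 h. Over the 20 sites with the highest mean count, the total at 4 h was 0.952 times that with DMSO, against 0.508 times over all tested sites. Of these 20 sites, 16 had a raw log2 change at 4 h within 0.3 of 0, and 1 fell in the raw comparison (edgeR adjusted p under 0.05). Counts at the 20 sites did not follow the difference between the controls either. Their DMSO B to A ratio was 0.985, against 1.68 over all tested sites. Retention of the fusion therefore cannot be read from these counts.

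**Figure D1:**
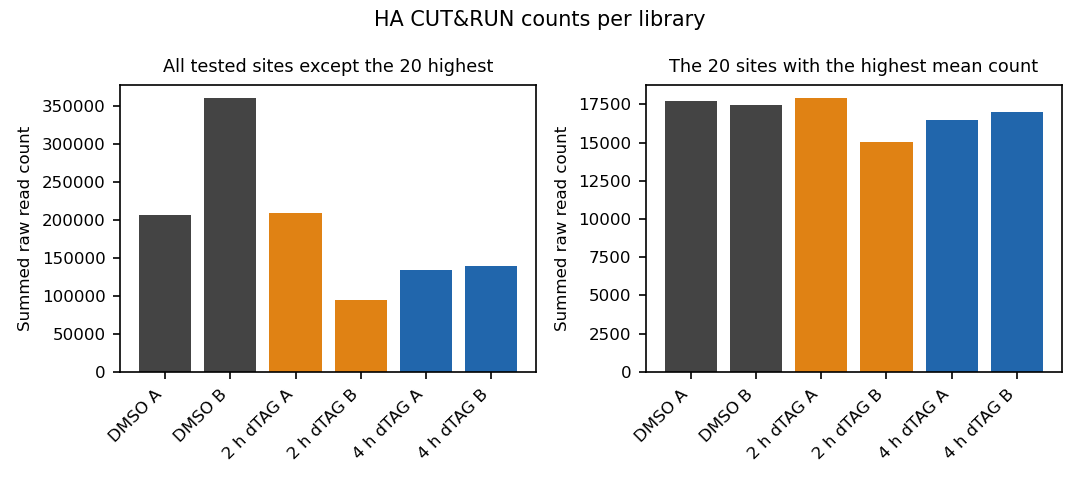
Summed raw read count (vertical axes, from 0) in each of the 6 libraries (bars) over all tested sites except the 20 with the highest mean count (left) and over those 20 sites (right). Totals on the right lie between 15013 and 17913, while those on the left run from 94759 to 360904.

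Comparing raw counts without any scaling asked which sites lost HA signal. At 2 h, 58 of 5575 sites fell and 0 rose (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At 4 h, 345 sites fell and 0 rose. Fitted counts were at least 4-fold lower at 197 sites at 2 h and at 435 sites (7.8%) at 4 h. In raw counts both 4 h columns lay below both DMSO libraries at 80.3% of the sites, and both 2 h libraries did so at 50.2%. Chance gives 16.7% for 2 libraries against 2, and 33.3% if the 4 h columns are 1 library. Both 4 h totals lay below both DMSO totals, which enters the raw share. With counts divided by each library's total in sites, both columns lay below at 34.8% of the sites and above at 19.05% at 4 h, and below at 32.7% and above at 15.35% at 2 h. Library-wide shifts enter this comparison and are shared by all sites, so its calls are not independent of each other. With the 4 h columns counted as 1 library, 0 sites were called at either time; leaving out the DMSO library B also gave 0 at both times, leaving out either 4 h column gave 0, and leaving out the 2 h library A gave 2092 at 2 h and 1385 at 4 h. Leaving out the 2 h library B gave 4 at 2 h and 1379 at 4 h.

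The largest falls left few reads. At chr4:104331557-104331957 there were 115 and 185 reads with DMSO, 35 and 17 at 2 h and 5 and 13 in the 4 h columns (raw log2 change at 4 h −4.04, SE 0.86). At chr5:42855673-42856073 the counts were 99 and 163 with DMSO, 31 and 4 at 2 h and 11 and 7 at 4 h. At chr2:225587943-225588343 they were 52 and 120 with DMSO, 14 and 7 at 2 h and 8 and 5 at 4 h. At chr17:27378220-27378620 they were 35 and 93 with DMSO, 16 and 2 at 2 h and 2 and 6 at 4 h. The site chr4:148932970-148933370 had 21 and 27 reads with DMSO, 9 and 3 at 2 h and 1 in each 4 h column. The edgeR adjusted p of the raw change at 4 h was between 0.000561 and 0.00301 at these 5 sites, and between 0.19 and 0.623 with the 4 h columns counted as 1 library.

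**Figure D2:**
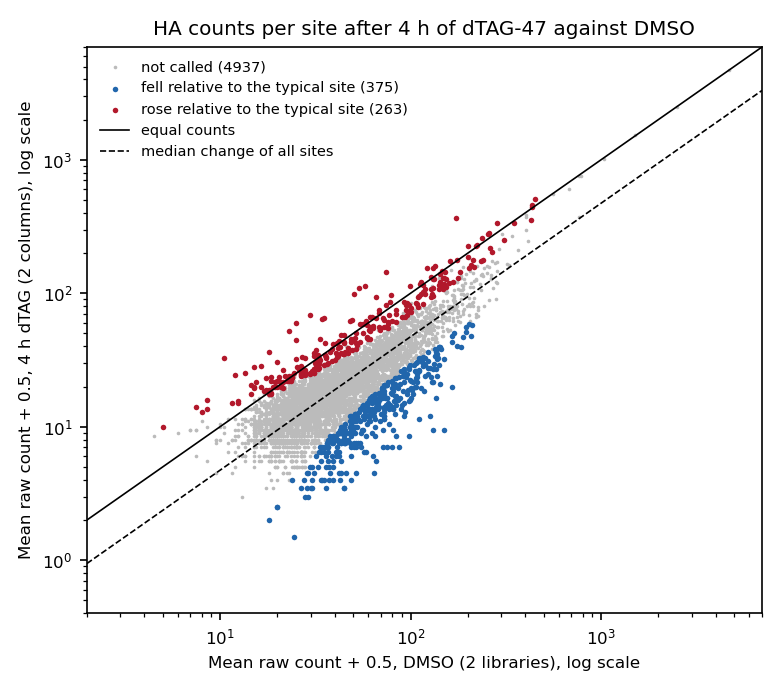
Mean raw count per site plus 0.5 with DMSO (horizontal, log scale) against that in the 4 h columns (vertical, log scale), with points coloured by the edgeR call relative to the typical site. Most points lie below the line of equal counts and along the dashed line of the median change; 375 sites fell and 263 rose relative to the typical site.

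A second comparison set each site against the typical site by TMM scaling, which removes any change common to most sites. It asked which sites lost more, or less, than the rest. At 2 h, 227 sites fell and 139 rose relative to the typical site (edgeR quasi-likelihood test, adjusted p under 0.05). At 4 h, 375 fell and 263 rose. The median raw change per site from DMSO to 4 h was a 5.03-fold fall over the 375 sites, against a 2.1-fold fall over the 4937 sites without a call. The 263 sites had a median raw log2 change of −0.07, and 167 of them lay within 0.3 of 0. These raw values follow largely from the near-constant shift between the scales (median log2 change of all sites 0.02 relative and −1.08 raw), so they describe the called sites in raw counts and are not a separate result. Chromosome Y stood apart, with 6 relative rises and 0 relative falls at 4 h among its 19 tested sites. Its median raw log2 change at 4 h was −0.11, against −1.21 to −0.96 on the other chromosomes. The reason was not tested.

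Single sites showed both kinds of change. At chr8:72515578-72515978, the largest relative fall at 2 h, there were 44 and 73 reads with DMSO, 5 and 3 at 2 h and 5 and 15 at 4 h (relative log2 change at 2 h −2.90, SE 0.405, edgeR adjusted p = 1.3e-05). At chr11:20249041-20249441 the counts were 36 and 47 with DMSO, 3 and 4 at 2 h and 3 and 5 at 4 h. At chr6:151863861-151864261 they were 58 and 87 with DMSO, 10 and 4 at 2 h and 10 and 12 at 4 h. At chr4:80074716-80075116 they were 54 and 104 with DMSO, 10 and 6 at 2 h and 7 and 6 at 4 h (relative log2 change at 4 h −2.48, SE 0.318, edgeR adjusted p = 9.3e-07). Among the sites that rose relative to the typical site, chr13:110076342-110076742 had 9 and 11 reads with DMSO, 28 and 20 at 2 h and 37 and 28 at 4 h (relative log2 change at 4 h 2.78, SE 0.338, edgeR adjusted p = 4.05e-07). At chr17:22020629-22021029 the counts were 140 and 204 with DMSO, 384 and 174 at 2 h and 404 and 330 at 4 h. At chr14:32953653-32954053 they were 39 and 67 with DMSO, 133 and 67 at 2 h and 112 and 106 at 4 h. At chr2:88124447-88124847 they were 42 and 72 with DMSO, 121 and 55 at 2 h and 133 and 92 at 4 h. In raw counts the edgeR adjusted p of these 4 rises at 4 h was between 0.0919 and 0.275.

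The split between falls and rises changed with the scaling, the test and the libraries. Scaling on total counts in sites gave 365 falls and 107 rises at 2 h and 564 and 180 at 4 h. Scaling on the 10% of sites with the lowest mean count gave 70 and 85 at 2 h and 187 and 151 at 4 h. Scaling on the 20 highest sites, chosen after seeing the data, gave 91 and 0 at 2 h and 477 and 1 at 4 h. The single rise there was chr17:22020629-22021029. With another test on the TMM scale, limma-voom gave 186 falls and 221 rises at 2 h and 292 and 348 at 4 h. DESeq2, which used its own size factors in place of TMM, called 28 sites at 2 h and 51 at 4 h, all of them among the edgeR calls. Its counts thus reflect a change of both test and scaling. Counting the 4 h columns as 1 library left 304 falls and 151 rises at 4 h. Leaving out the 2 h library A turned the split at 2 h, to 92 falls and 159 rises. Leaving out the DMSO library B gave 96 calls at 2 h and 269 at 4 h, leaving out the 2 h library B gave 210 at 2 h, and leaving out 4 h column A or B gave 258 or 217 at 4 h.

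**Figure D3:**
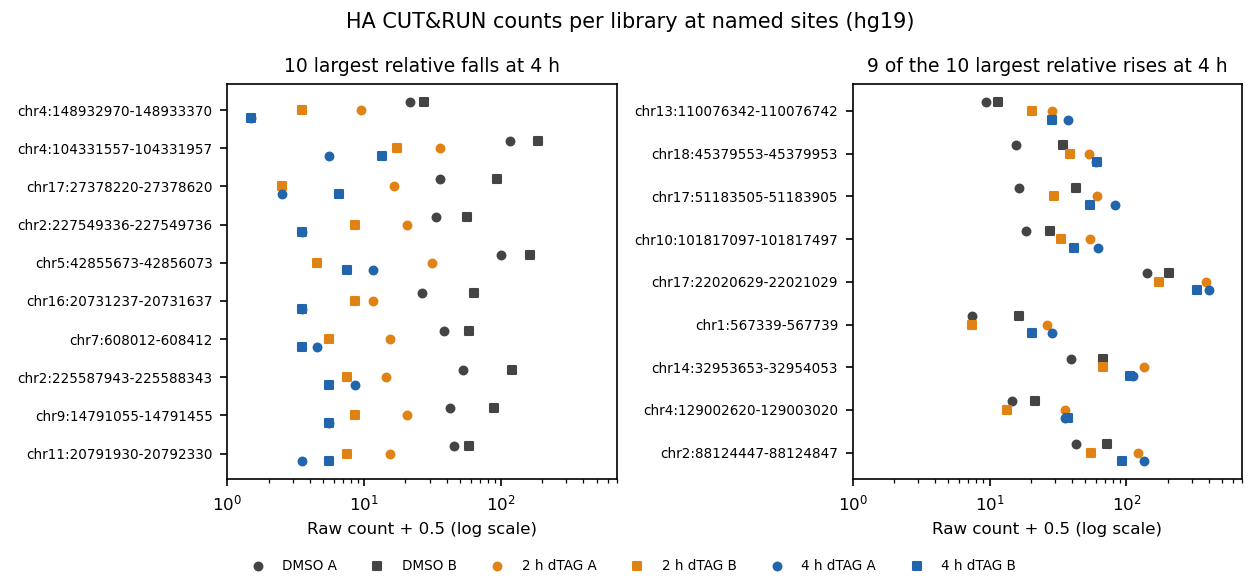
Raw count plus 0.5 (horizontal, log scale) in each of the 6 libraries (points) at the 10 sites with the largest relative fall at 4 h and at 9 of the 10 with the largest relative rise. The rise left out is chrY:13483746-13484146, with 3 and 6 reads with DMSO and 10 and 9 at 4 h. At chr4:148932970-148933370 both 4 h columns hold 1 read, against 21 and 27 with DMSO.

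Strong and weak sites had similar median losses of raw counts. With the sites split into 3 equal classes by mean count over the 6 libraries, the median raw log2 change at 4 h was −1.09 in the lowest, −1.08 in the middle and −1.08 in the highest class. Relative falls at 4 h numbered 81, 125 and 169 from the lowest to the highest class, and relative rises 35, 65 and 163. In the raw comparison the order was the reverse, with 195, 88 and 62 falls at 4 h and 43, 12 and 3 at 2 h. Which class held the most falls thus changed with the fit, and the reason was not tested. Whether the relative counts differ beyond the higher power at sites with more reads was not tested either.

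The 2 treatment times were compared to ask whether loss went on after 2 h. No site was called between 4 h and 2 h. The edgeR test of raw counts gave 0 sites, with 11 at an unadjusted p under 0.05, and the relative test gave 0, with 321 at an unadjusted p under 0.05. DESeq2 also gave 0, with 8 and 29 at an unadjusted p under 0.05, as did limma-voom, with 31 and 300. The median raw log2 change from 2 h to 4 h was −0.17, but it was 0.53 without the 2 h library A and −0.63 without the 2 h library B, so its direction rests on 1 library. At chr4:104331557-104331957 the relative log2 change from 2 h to 4 h was −1.36 (SE 0.371, edgeR adjusted p = 0.674).

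The sites called at 2 h were largely called again at 4 h. Of the 227 relative falls at 2 h, 178 also fell at 4 h, and of the 139 rises 107 also rose, with 0 sites in opposite directions. Independent lists would share 15.3 falls and 6.56 rises, without any allowance for the shared controls. In 20 simulated sets all 6 columns, DMSO included, were drawn without change, and both times were set against the same simulated controls. The calls of both times shared at most 0 sites there, which says nothing on the overlap because unchanged groups give almost no calls. Over the 178 shared falls, the median raw change per site against DMSO was a 4.44-fold fall at 2 h and a 5.66-fold fall at 4 h. Across sites, which are not independent replicates, the relative log2 changes at 2 h and 4 h had a Pearson r of 0.775, against 0.348 in the simulated sets. Their covariance was 0.244, against 0.0366 simulated. The raw log2 changes had an r of 0.777 against 0.502 simulated, and a covariance of 0.245 against 0.208 simulated. In a check chosen after seeing the data, 2 h was set against 1 DMSO library and 4 h against the other, which leaves 1 control library each. The covariance of the relative changes was then 0.197 and 0.206 in the 2 arrangements, and that of the raw changes 0.194 and 0.205, so the simulated raw value does not measure what the shared controls gave. Relative falls shared by both times then numbered 50 and 96, where independent lists give 3.96 and 7.16, and shared rises 25 and 31, where they give 1.61 and 3.0. The raw calls shared 0 sites in either arrangement, because 1 of the times had 0 calls in each.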

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

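Scaling on the 20 highest sites and counting the 4 h columns as 1 library were chosen after seeing the data. Over the comparisons with DMSO, 31 alternative counts of called sites stayed within 1.5 times the reported count and 33 did not. The 4 h against 2 h counts were 0 under all 32 alternatives run, which is no sign of stability. None of the 40 largest relative falls and rises reversed its direction under the alternative tests, filters, scalings and left-out libraries. Some sites are in the lists of both times. All were chosen for large changes and separated columns in these same counts, so a reversal was unlikely and its absence is no support. DESeq2 ended the call at 11 and scaling on the 20 highest sites at 19.

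Raw calls at 2 h (58) became 0 with only the compared groups in the fit, 180 with limma-voom, 155 scaled on the lowest 10% of sites, 91 scaled on the 20 highest sites, and 0 with the 4 h columns as 1 library, and ranged from 0 to 2092 leaving out 1 library. Raw calls at 4 h (345) became 1374 with only the compared groups and 0 with the 4 h columns as 1 library, and ranged from 0 to 1385 leaving out 1 library; scaled on the lowest 10% they were 187 falls and 151 rises. Relative calls at 2 h (366) became 28 with DESeq2, 155 scaled on the lowest 10%, 91 scaled on the 20 highest sites and 239 with a minimum log2 change of 1, and ranged from 96 to 406 leaving out 1 library. Relative calls at 4 h (638) became 51 with DESeq2, 338 scaled on the lowest 10% and 404 with the minimum change, and ranged from 217 to 774. The minimum change removes calls by construction; the cause was not tested for the others. Where 1 library was left, it was assumed to vary like the other groups.

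With the column letter as a replicate block, raw calls were 0 at 2 h and 1 at 4 h, and relative calls 173 and 433. The letters did not pair libraries: their A minus B differences correlated at −0.199, 0.0116 and −0.00926 between groups.

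The median log2 change at 4 h was −1.08 unscaled, −1.06 scaled on the 20 highest sites, −0.11 on totals, 0.02 with TMM and 0.10 on the lowest 10%, so the size of a common loss rests on the scale chosen. In 5 equal classes of the sites by mean count, from the lowest to the highest, relative falls at 4 h were 35, 67, 70, 110 and 93. Raw falls at 4 h were 131, 87, 49, 45 and 33. Alternatives with the library without crosslinking, and the distances to genes, were not run.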

Other observations

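The tests of read depth, of a single 4 h library, of a constant signal and of a common source were settled after their results were seen, as were the definition of the 19 sites with higher counts and the bands of distance. For the common source, the limit of 1.5 was set before and the comparison with other sets after; for the constant signal, the DMSO ratio replaced a 4 h to DMSO ratio that the choice of sites fixes. The other tests were written before their results.

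A small set of 19 sites was picked for higher raw counts at 4 h (relative rise at 4 h, raw log2 change of at least 0.75 and mean count of at least 10). Their pooled counts were 528 and 817 in the DMSO libraries A and B, 1532 and 770 in the 2 h libraries A and B, and 1530 and 1238 in the 4 h columns. The 4 h to DMSO ratio of 2.06 is set by the choice of sites. The 2 h to DMSO ratio was 1.71 in pooled raw counts, although the 2 h library B held fewer of these reads than the DMSO library B. As a share of each library's counts, the 19 sites held 0.235% and 0.216% with DMSO and 0.674% and 0.7015% in the 2 h libraries A and B. They held 1.02% and 0.794% at 4 h. The choice used the same DMSO libraries, so DMSO counts low by sampling raise the 2 h to DMSO ratio and lower the DMSO shares too. By how much was not tested. The set included chr17:22020629-22021029, chr13:110076342-110076742 and chr14:32953653-32954053, described above. At chr5:79947928-79948328 there were 30 and 39 reads with DMSO, 85 and 47 at 2 h and 74 and 56 at 4 h. At chr5:93906389-93906789 there were 59 and 89 reads with DMSO, 152 and 88 at 2 h and 167 and 119 at 4 h. None of the 19 was called in raw counts.

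These 19 sites do not follow the constant signal of the 20 highest sites, since their DMSO B to A ratio was 1.55 (bootstrap interval 1.43 to 1.71 over sites) against 0.985 for the 20 highest. A second candidate explanation is reads of 1 common source, such as mitochondrial DNA, placed at several nuclear positions. Their counts shared 1 profile over the libraries (chi-square per degree of freedom 0.924). Only 0.1% of 1000 random sets matched on mean count were as low, but 11.6% of 1000 sets drawn from sites that fell in an equally wide band were, so a common source cannot be told apart from sites chosen for a like change. No annotation of such insertions was used here, and a true gain of HA signal stays open.

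The 2 h libraries differed 2.07-fold in total count over tested sites. A difference in read depth would scale the 20 highest sites too, but these differed 1.19-fold (bootstrap interval 1.13 to 1.33). That reading assumes that counts at those sites follow depth, which was not tested. Counts at the 20 highest sites also stayed level between the DMSO libraries (B to A 0.985, against 1.68 over all tested sites). Less complete removal of the fusion in library A could leave it more signal at the sites that fell at 4 h. Scaled by TMM, A over B there was 1.02 (0.982 to 1.06), which includes 1. As a share of each library's counts, these sites held 4.94% in A and 4.49% in B. The answer thus turns on the scaling, and less complete removal cannot be told apart from a change common to all sites. Differences in antibody or nuclease yield were not tested and stay open.

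The 4 h columns agreed within sampling noise (chi-square per degree of freedom 1.01). This is consistent with both columns coming from 1 library, while the DMSO and 2 h pairs differed by more (2.09 and 1.96). Without the 20 highest sites the pairs came closer, at 1.54 for DMSO, 1.43 for 2 h and 1.01 for 4 h, and the 2 h library B differed from the 4 h columns by only 1.16 and 1.19 despite its other treatment. Very similar separate libraries would give the same value as 1 library, and nothing in the counts decides between these.

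A hypothesis was that neighbouring sites change alike. Across 421 pairs of neighbouring sites within 10 kb, the relative log2 changes at 4 h had a Pearson r of 0.614 and a Spearman rho of 0.632 (permutation p = 0.0001, the smallest that 10000 permutations within 10 classes of mean count can give). The r was 0.593 for gaps of 1 to 10 kb, 0.201 for 10 to 100 kb and 0.0591 beyond 100 kb. Leaving out sites that rose, r within 10 kb was 0.452. Both sites fell in 6 pairs, against 1.9 if calls were independent. Pairs share regions, so they are not independent replicates, and local effects of sequence or mapping may give the same pattern as shared loss of the fusion.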
